A study of Mus musculus with 10 samples.

How the data were processed

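The series holds 10 RNA libraries of mouse ear skin: 4 with imiquimod and DMSO, 4 with imiquimod and benzamil, and 2 untreated. Per the labels, 500 ng of RNA went into a 3' mRNA library kit with unique molecular identifiers, sequenced with a 150-cycle kit. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the mm10 genome, and their versions are not given in the sources used here. Whether reads with the same molecular identifier were collapsed is not stated, so intervals and floors below cover counting error only. Such 3' libraries give 1 fragment near the end of each transcript, so read numbers are not divided by gene length.

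The authors deposited 2 tables of log2 values for mouse genes, named as variance-stabilised values of DESeq2. The table with benzamil and DMSO libraries holds 10653 genes and the table with untreated and DMSO libraries 9820. Each was normalized on its own. The authors also deposited 2 DESeq2 result tables with a mean signal (counts divided by size factors), a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted p-value. Their untreated table is coded as untreated minus DMSO. A further deposited table holds counts per gene, but all of its 61533 identifiers are human and 0 are mouse, although the labels give mouse samples and mm10. This count table was not used in any comparison and is described only among the results for a closer look.

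The deposited log2 values were turned back into reads. The variance-stabilising transform was inverted from its value at 0 reads, and each library's step gave the worth of 1 read. In every library 100% of values came out whole within 0.001 reads, the mean over libraries equalled the authors' mean signal, and 39116 of 39116 DMSO values present in both tables gave equal reads. On simulated data the inversion returned 80000 of 80000 values for each table. The lowest gene total was 10 reads in each table. The 9779 genes present in both tables were joined, which left out 874 genes of the benzamil table and 41 of the untreated table. Scnn1b, Scnn1g and Il17a were therefore not analysed here. Genes absent from the untreated table presumably had few DMSO and untreated reads, so the join may leave out some genes that were higher with benzamil. Coordinates come from GENCODE M21 on mm10, where 9698 of 9779 identifiers were found and 9503 had the same symbol.

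The test fixed before the data were examined was edgeR's quasi-likelihood test on a count table. The deposited mouse values were log2 values instead. The test was kept and run on the recovered reads, and limma on the deposited log2 values was added as an alternative chosen after seeing the data. A reader who takes the deposited unit as decisive would make limma the principal test. In benzamil over DMSO limma gave 423 higher and 754 lower genes, and 962 of the 1155 edgeR genes were among them with the same direction. In DMSO over untreated it gave 2369 higher and 541 lower. Benzamil over untreated could not be tested with limma, since the 2 tables were normalized separately.

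These tests were compared on simulated reads, also after seeing the data. In 10 simulations of unchanged groups over 9779 genes, edgeR called 0.2 genes on average for benzamil over DMSO and 0 for DMSO over untreated, and limma 0 and 0.7, so neither was in excess. With the called genes changed by their fitted fold, of at most 16, edgeR made 887.8 calls with 3.05% on unchanged genes for benzamil over DMSO, and limma 806.9 with 2.71%. For DMSO over untreated edgeR made 776.7 calls with 4.47% on unchanged genes, and limma 1110.9 with 36.5%, of which 96% were in the higher direction. These reads were drawn with the spread that edgeR fitted, and only genes called by edgeR were changed, so the setting favours edgeR. The 1110.9 simulated limma calls also fell short of limma's 2910 calls on the deposited values. This simulation therefore cannot show that limma's further calls are false. edgeR was chosen, and the choice reconsidered and kept, before the counts of limma were known. All simulations were run after limma's 2369 higher genes had been seen, to look for a reason, and the choice was then looked at again and left. The 1st simulation, of unchanged groups over the 5245 genes edgeR tested, showed no fault in limma, the wider simulation over 9779 genes showed none either, and only the last, with changed genes, separated the tests, and only for DMSO over untreated.

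All 10 libraries entered 1 edgeR fit (version 4.0.16, R 4.3.3) with a mean per group, TMM scaling and no covariate. filterByExpr kept 5245 genes (at least 10 reads at the typical depth and a total of 15). The common biological coefficient of variation was 0.195. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. In edgeR, 1851 genes had an unadjusted p under 0.05 for benzamil over DMSO, 1746 for DMSO over untreated and 992 for benzamil over untreated. Groups that do not overlap arise by chance in 2.86% of genes with 4 against 4 libraries and in 13.3% with 4 against 2. CPM values use TMM-scaled library sizes, except those of Xist and of 1 or 3 reads per library, which use the library total. For a group with 0 reads a bound was set with a floor of 3 reads over the group, and for a group with 1 to 3 reads the ratio is given with its exact 95% counting interval.

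In all, 33 gene lists of pathways and cell types were fixed before the data were examined, and 18 had at least 4 tested members. They were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Named genes follow a rule fixed at the same time: up to 10 higher and 10 lower genes per comparison with the largest fold change, a mean of at least 10 CPM and no overlap between groups, up to 4 members per list, and Scnn1a, Scnn1b, Scnn1g, Sgk1, S100a8, S100a9, Krt6a, Krt16, Lcn2, Il1b and Il17a always. Tnip1, Wfdc21, Xist, Ddx3y and the members of the lists under other observations fall outside the rule and were named after their values were seen.

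The fit was tested on simulated counts with genes changed by known folds. For benzamil over DMSO (4934 genes) it recovered 51.6% of 93 genes changed 2-fold and 95.5% of 88 changed 4-fold, with 4.35% of calls on unchanged genes. For DMSO over untreated (4940 genes) it recovered 5.43% and 45.8%, and for benzamil over untreated (4939 genes) 5.26% and 45.2%, with 0 calls on unchanged genes. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 1.93 to 6.87, so none was treated as a duplicate.

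Alternatives fixed beforehand were DESeq2 size factors, no composition scaling, no filter, a filter at 10 CPM, DESeq2 (1.42.0), limma-voom (limma 3.58.1), fits of 2 groups, a replicate block, thinning to the smallest library, removal of the 50 most abundant genes, an estimated correlation, splits of the DMSO libraries and leaving out each library. Alternatives added after seeing the data were a filter at 100 CPM, limma on the deposited log2 values, removal of ribosomal RNA genes, and benzamil libraries 3 and 4 left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the recovery and the plots. The tests of depth were at first made on the genes that passed the filter after thinning, and were replaced by tests on all members, since the change itself can decide which genes pass. The test of the non-epidermal share was at first a permutation over list members, and was replaced by a test over libraries because members of a list vary together. The test of transcript length and GC content was at first made on the stress keratin list alone, and was replaced by a test on all genes called higher against untreated skin. Values of 3 further genes are not reported here.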

Results

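RNA was measured in ear skin of C57BL/6 mice aged 6 to 8 weeks in 3 groups. The DMSO group (n = 4) received topical imiquimod, a Toll-like receptor agonist that causes psoriasis-like inflammation in mouse skin, together with the solvent DMSO. The benzamil group (n = 4) received imiquimod with benzamil, an amiloride analog that blocks the epithelial sodium channel. The remaining group was untreated (n = 2). Treatment lasted 6 days per the labels. The sample labels name ear skin for every library, whereas the series' design text speaks of back skin for the untreated control, so a difference in body site between the untreated and treated libraries stays open. No label says that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical.

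Libraries were shallow. They held 938322, 362021, 260207 and 354112 reads in DMSO libraries 1 to 4, 377240, 314999, 208153 and 139204 in benzamil libraries 1 to 4, and 74713 and 71230 in untreated libraries 1 and 2. A single read was worth 1.07 CPM, the count scaled by library total, in DMSO library 1 and 14.1 CPM in untreated library 2, so many genes with 0 reads in untreated skin lay under a limit of up to 42.2 CPM per library (3 reads). Ribosomal RNA genes (mt-Rnr1, mt-Rnr2 and Rn18s-rs5) took 22.1% to 28.8% of the reads in the DMSO group, 31.0% to 45.7% in the benzamil group, and 34.2% and 38.6% in the untreated libraries. Most of these reads were of mitochondrial mt-Rnr2, with 13.5% to 19.3%, 24.0% to 39.6%, and 26.3% and 24.2% in the same order. The 1st principal component held 43.1% of the variance. Values below are log2 fold changes ± standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 5245 genes, and group levels are mean CPM ± SD. The test gives no standard error itself. The value printed is approximate, the absolute log2 fold change divided by the square root of the test's F statistic.

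The comparison of the benzamil group with the DMSO group asked how the channel blocker changed the transcriptome of imiquimod-treated skin. Genes of inflamed epidermis were lower with benzamil. Krt6b, a keratin of wounded and hyperproliferative epidermis, fell from 2434 ± 1223 to 251 ± 160 CPM (n = 4 and 4), and the neutrophil and keratinocyte alarmin S100a8 fell from 7573 ± 1796 to 910 ± 1113 CPM. The filaggrin family member Flg2 rose from 217 ± 112 to 1493 ± 516 CPM, against 2266 ± 184 CPM in untreated skin (n = 2). Only 3 of 35 tested differentiation genes, Flg2 among them, were called lower with DMSO than in untreated skin, and 12 were called higher. In all, 520 genes were higher and 635 lower with benzamil.

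The list of stress keratins and cornified-envelope genes of inflamed epidermis moved most. Of its 25 tested members, 22 fell and none rose (24 fell when adjusted over the list alone), with a median log2 fold change of -2.12 (camera adjusted p = 1.2e-24). The call was lost with an estimated correlation (adjusted p = 0.127). Krt6b (chromosome 15, 101676023 to 101680287, mm10) changed by -3.31 ± 0.37 (edgeR adjusted p = 2.28e-06), Krt6a by -2.06 ± 0.31 (edgeR adjusted p = 5.87e-05), and the cystatin-family gene Stfa1 by -2.71 ± 0.31 (edgeR adjusted p = 3.21e-06). Among the small proline-rich proteins, which are cross-linked into the cornified envelope, Sprr2g changed by -4.52 ± 0.53 (-6.01 without benzamil library 4), Sprr2f by -3.95 ± 0.51 and the late cornified envelope gene Lce3a by -4.37 ± 0.56. Sprr2b had 415 reads in the DMSO group and 0 in the benzamil group, at least 63.7-fold lower against a floor of 3 reads over the group. Krt16 was 2168 ± 313 CPM with DMSO and 1165 ± 1300 CPM with benzamil and did not pass the test (-0.93 ± 0.40, edgeR adjusted p = 0.0948). Benzamil library 4 carried that level, with 3113 CPM against 440 to 604 CPM in the other 3, and without it Krt16 changed by -2.06 (adjusted p = 1.9e-06). Sprr, Stfa, Lce and Krt6 genes have near-identical copies, so reads may be split between their members.

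Of 13 tested antimicrobial proteins and alarmins, 10 fell and Wfdc21 rose (the same numbers when adjusted over the list alone), with a median of -2.01 (camera adjusted p = 5.22e-06, and adjusted p = 0.127 with an estimated correlation). S100a8 (chromosome 3, 90668978 to 90670035) changed by -3.09 ± 0.55 (edgeR adjusted p = 0.000301) and S100a9, the other subunit of calprotectin, by -3.25 ± 0.49 (edgeR adjusted p = 5.44e-05). The defensins Defb3 and Defb6 changed by -2.42 ± 0.43 and -1.25 ± 0.21. Defb4 had 94 reads with DMSO and 2 with benzamil, a ratio of 21.6 with a counting interval of 5.83 to 181. All its benzamil reads were in library 4. Its log2 fold change was -4.18, and -6.95 without that library, when no benzamil read remained. Lcn2, an iron-sequestering protein of inflamed epithelia, changed by -2.01 ± 0.51 (edgeR adjusted p = 0.00617), which became adjusted p = 0.0524 without benzamil library 1. Benzamil library 4 had 79.4 CPM of Lcn2 against 0 to 9.1 CPM in the other 3, and without it Lcn2 changed by -3.39 (adjusted p = 5.97e-05).

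Among 6 tested cytokines of the IL-17, IL-23 and IL-36 axis 4 fell (4 when adjusted over the list alone), with a median of -1.20 (camera adjusted p = 0.000569, and adjusted p = 0.127 with an estimated correlation). They were Il1b (-3.26 ± 0.63, edgeR adjusted p = 0.000727), Il19 (-3.06 ± 0.60, and -4.55 without benzamil library 4), Il36a (-1.12 ± 0.22) and Il36b (-1.27 ± 0.33, with adjusted p = 0.0654 without benzamil libraries 3 and 4). Of 8 tested NF-kB targets 6 fell and Tnip1 rose (7 and 1 over the list alone), with a median of -1.56 (camera adjusted p = 0.000113, and adjusted p = 0.127 with an estimated correlation). Nfkbia, the inhibitor induced by NF-kB, changed by -1.83 ± 0.25, Bcl3 by -2.07 ± 0.35 and Sod2 by -1.82 ± 0.33. Of 14 tested immediate early genes 5 fell (6 over the list alone), among them Junb by -2.31 ± 0.34 (camera adjusted p = 0.00415, and adjusted p = 0.197 with an estimated correlation). The chemokine Ccl20, which attracts CCR6-bearing T cells, had 79 reads with DMSO and 1 with benzamil, a ratio of 36.4 with a counting interval of 6.35 to 1455. Of 4 tested chemokines 2 fell (2 over the list alone) and the list did not pass (camera adjusted p = 0.0831). It passed without DMSO library 2 (0.0414), DMSO library 4 (0.0449) or benzamil library 4 (0.0305).

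Of 28 tested cell cycle genes 7 fell and none rose (8 fell when adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.000158, and adjusted p = 0.23 with an estimated correlation). Cdc20 changed by -1.98 ± 0.44, Mcm6 by -1.80 ± 0.40 and Cdk1 by -1.59 ± 0.38. Epgn, which encodes a ligand of the epidermal growth factor receptor, changed by -4.00 ± 0.60 (edgeR adjusted p = 5.56e-05).

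Of 35 tested genes of epidermal differentiation 19 rose and Rptn and Tgm1 fell (21 and 3 when adjusted over the list alone), with a median of 0.80 (camera adjusted p = 8.58e-08, and adjusted p = 0.23 with an estimated correlation). Flg2 (chromosome 3, 93197278 to 93221391) changed by 2.81 ± 0.28 (edgeR adjusted p = 4.87e-07), Krt2, a keratin of the upper spinous and granular layers, by 1.65 ± 0.28 (edgeR adjusted p = 0.000207) and Lce1m by 1.93 ± 0.29. The list's mean log2 CPM was 7.33 in untreated skin, 8.22 with DMSO and 8.96 with benzamil. Unlike Flg2, the list as a whole thus lay further from untreated skin with benzamil than with DMSO. The treated groups overlapped, with 8.62 in DMSO library 3 against 8.57 in benzamil library 4. The genes outside the lists with the largest increases were Fmo2 (3.35 ± 0.40), the epidermal metallothionein Mt4 (3.00 ± 0.32) and the growth factor Btc (2.88 ± 0.46). Sebaceous gland genes rose in 6 of 13 (8 higher and 2 lower over the list alone), with a median of 0.61 (camera adjusted p = 0.000497, and adjusted p = 0.23 with an estimated correlation). Among these lipid-synthesis genes Elovl6 changed by 1.41 ± 0.22, Fasn by 1.51 ± 0.29 and Scd1 by 1.17 ± 0.25.

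Of 16 tested skeletal muscle genes 9 rose with benzamil (12 over the list alone), with a median of 1.32 (camera adjusted p = 3.82e-05, and adjusted p = 0.277 with an estimated correlation), and Myl1 changed by 2.25 ± 0.39. The groups overlapped in the list's mean log2 CPM, with 6.76 in DMSO library 3 against 6.19 and 5.99 in benzamil libraries 3 and 4. The calls of Acta1, Myh1 and Myh4 were each lost when 1 library was left out. These genes did not pass in the authors' DESeq2 results either (adjusted p = 0.282, 0.298 and 0.316). Of 14 tested fibroblast and matrix genes 3 rose (4 over the list alone), with a median of 0.64 (camera adjusted p = 0.0093, and adjusted p = 0.476 with an estimated correlation), and Sparc changed by 1.66 ± 0.30. The groups overlapped in the matrix list's mean log2 CPM as well, with 5.47 in benzamil library 3 against 5.40 to 6.10 with DMSO. The matrix list's adjusted p was 0.0661 without benzamil library 4. Basal keratinocyte genes rose in 4 of 12 (5 over the list alone), with a median of 0.27 (camera adjusted p = 0.0358, and adjusted p = 0.19 with an estimated correlation), led by Dst (1.58 ± 0.22) and Krt15 (1.17 ± 0.28). That list's adjusted p was 0.0534 without DMSO library 3 and 0.0772 without DMSO library 4.

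The genes of the drug's target were measured at low depth. Scnn1a, the channel's alpha subunit (chromosome 6, 125320659 to 125344943), was 47.4 ± 11.3 CPM with DMSO and 46 ± 17.4 CPM with benzamil (-0.05 ± 0.35, edgeR adjusted p = 0.948), and the channel-activating kinase Sgk1 gave -0.08 ± 0.32 (edgeR adjusted p = 0.887, and -0.67 without benzamil library 1, which stood apart). Of 15 tested genes of sodium transport 2 rose (2 over the list alone), the cotransporter Slc12a2 by 1.04 ± 0.21 and the protease Furin by 0.88 ± 0.24, and the list did not pass (camera adjusted p = 0.7). Furin lost its call with total counts alone (0.60, adjusted p = 0.0859), after thinning (0.58, adjusted p = 0.26) and without benzamil libraries 3 and 4 (0.64, adjusted p = 0.124).

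Lists that did not pass gave these counts. Barrier lipid synthesis had 1 of 19 higher, Elovl4, and 2 lower, Degs1 and Sptlc2 (camera adjusted p = 0.827), and without benzamil libraries 3 and 4 Elovl4 gave an adjusted p of 0.0607 and Sptlc2 of 0.0947. Cholesterol synthesis had 4 of 18 higher and 2 lower (camera adjusted p = 0.844), with a median of -0.20 and a mean of 0.02. Glycolysis had 3 of 9 lower (camera adjusted p = 0.116), and mitochondrially encoded genes had 2 of 6 lower (camera adjusted p = 0.118, and 0.03 without benzamil library 2). Dendritic and Langerhans cell markers had 0 of 4 changed (camera adjusted p = 0.894). For lists with fewer than 4 tested genes, the neutrophil receptor Cxcr2 changed by -1.88 ± 0.43, Gpnmb by 2.32 ± 0.47 and Gata3 by 0.83 ± 0.19. Values without a call were 0.15 ± 0.24 for the T cell gene Thy1, 0.44 ± 0.28 for the adipocyte gene Lpl, 0.14 ± 0.28 for the cartilage gene Sox9 and -0.20 ± 0.51 for the globin Hbb-bs, which turned to 1.10 without DMSO library 1. Type I interferon, mast cell, B and plasma cell, endothelial, hair follicle and trunk homeobox lists had 0 tested members.

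In total, 11 of the 18 testable lists passed with the preset correlation and 0 with an estimated one. Without DMSO library 1 the comparison gave 291 higher and 356 lower genes, without DMSO library 2 346 higher, without benzamil library 3 332 higher, and without benzamil libraries 3 and 4 284 higher and 300 lower. Scaling by total counts alone shifted the median of all genes by -0.26 and gave 248 higher and 1009 lower genes, 19.7% higher against 45.0%.

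**Figure D1:**
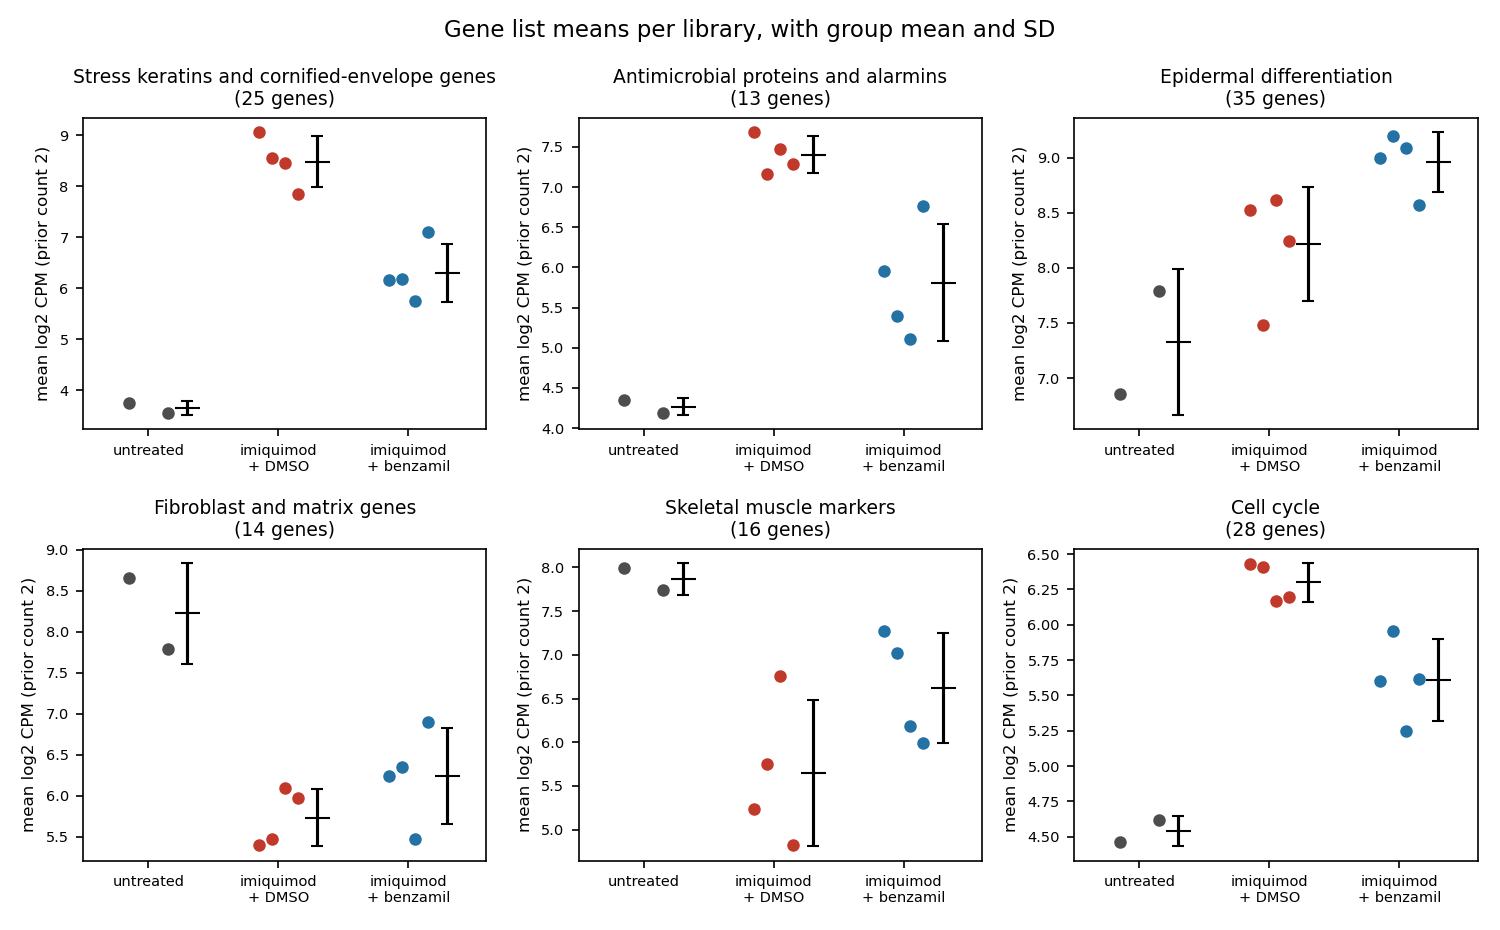
Mean log2 CPM (prior count of 2) over the members of 6 gene lists in each library, with 1 point per library and a bar for the group mean ± SD (untreated n = 2, imiquimod with DMSO n = 4, imiquimod with benzamil n = 4). Stress keratins averaged 3.65, 8.49 and 6.30 in the untreated, DMSO and benzamil groups, and matrix genes 8.23, 5.73 and 6.24.

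The comparison of the DMSO group with untreated skin asked what imiquimod with its vehicle changed, and imiquimod and DMSO cannot be told apart in it. Krt6a rose from 85.6 ± 25.8 to 3028 ± 994 CPM, the cystatin-family gene Stfa3 from 35 ± 7.6 to 3177 ± 238 CPM and S100a8 from 74.7 ± 84.7 to 7573 ± 1796 CPM (n = 2 and 4). Col1a1, which encodes the main chain of type I collagen, fell from 6098 ± 4681 to 163 ± 88.7 CPM. In all, 521 genes were higher and 443 lower.

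Of 25 stress keratin and cornified-envelope genes 24 rose (25 over the list alone; camera adjusted p = 6.09e-31, and adjusted p = 0.0633 with an estimated correlation). Their median was 8.46, or 3.77 with the 15 members that had 0 untreated reads set at their bound. Stfa3 changed by 6.48 ± 0.54 (edgeR adjusted p = 4.02e-09), Krt6a by 5.15 ± 0.58 (edgeR adjusted p = 9.94e-07) and Krt16 by 6.25 ± 0.92 (edgeR adjusted p = 3.89e-05). Krt6b had 3 untreated reads, a ratio of 131 with a counting interval of 44.7 to 635. Genes with 0 untreated reads were at least 48.0-fold higher for Sprr1b, at least 31.3-fold higher for Stfa1 and at least 11.4-fold higher for the cystine transporter Slc7a11.

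Of 13 antimicrobial genes 5 rose and Wfdc21 fell (9 and 1 over the list alone), with a median of 5.97, or 1.76 at the bound (camera adjusted p = 2.48e-06, and adjusted p = 0.078 with an estimated correlation). S100a8 changed by 6.61 ± 1.03, S100a9 by 7.09 ± 0.94 and Defb6 by 3.44 ± 0.40. Of 6 IL-17, IL-23 and IL-36 axis cytokines 5 rose (5 over the list alone), with a median of 6.26, or 1.78 at the bound (camera adjusted p = 0.000698, and adjusted p = 0.078 with an estimated correlation), and Il36a had 524 reads against 1, a ratio of 37.8 with a counting interval of 6.75 to 1496. NF-kB targets rose in 4 of 8 (6 over the list alone; camera adjusted p = 0.0043, and adjusted p = 0.078 with an estimated correlation), and Bcl3 was at least 4.14-fold higher. Cell cycle genes rose in 10 of 28 (16 over the list alone), with a median of 1.95, or 1.23 at the bound (camera adjusted p = 0.000195, and adjusted p = 0.197 with an estimated correlation), and Ccna2 was at least 3.27-fold higher. Immediate early genes had 6 of 14 higher and the list did not pass (camera adjusted p = 0.0945), and chemokines had 1 of 4 higher (camera adjusted p = 0.215).

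Differentiation genes moved in both directions. Of 35, 12 rose and 3 fell (14 and 3 over the list alone), with a median of 0.87 (camera adjusted p = 0.00197, and adjusted p = 0.468 with an estimated correlation). Krt1, an early differentiation keratin, changed by 4.27 ± 0.41 (edgeR adjusted p = 5.17e-08) and the desquamation protease Klk7 by 2.76 ± 0.34, whereas Flg2 changed by -3.41 ± 0.32 (edgeR adjusted p = 4.63e-08). The list's adjusted p was 0.266 without untreated library 1. Basal keratinocyte genes had 2 of 12 higher and 3 lower (2 and 4 over the list alone), with a median of -0.67 (camera adjusted p = 0.00494, and adjusted p = 0.078 with an estimated correlation). Krt15, a keratin of follicle stem cells and resting basal cells, changed by -3.18 ± 0.33, Dst by -2.23 ± 0.26 and Krt14 by 1.32 ± 0.29.

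Barrier lipid synthesis rose in 7 of 19 (8 over the list alone; camera adjusted p = 0.00186, and adjusted p = 0.128 with an estimated correlation), and Degs1 changed by 1.68 ± 0.36. Cholesterol synthesis had 5 of 18 higher and 1 lower (5 and 1 over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.162 with an estimated correlation), and Sqle changed by 2.45 ± 0.49. Glycolysis had 2 of 9 higher (3 over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.162 with an estimated correlation), and Ldha changed by 1.60 ± 0.31. The cholesterol and glycolysis lists each had an adjusted p of 0.0822 without untreated library 2. Lists of sodium transport (camera adjusted p = 0.605), sebaceous gland (0.567), mitochondrially encoded (0.459) and dendritic cell genes (0.511) did not pass, and Scd1 of the sebaceous list changed by -1.73 ± 0.30. Scnn1a had 84 reads against 2, a ratio of 3.03 with a counting interval of 0.813 to 25.4.

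Matrix and muscle genes were lower in the DMSO group. Of 14 matrix genes 11 fell (11 over the list alone), with a median of -3.39 (camera adjusted p = 3.72e-24, and adjusted p = 0.0633 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042) changed by -5.29 ± 0.44 (edgeR adjusted p = 4.02e-09), Col1a2 by -4.24 ± 0.32 (edgeR adjusted p = 7.84e-10) and Sparc by -4.44 ± 0.34 (edgeR adjusted p = 1.26e-09). Of 16 muscle genes 12 fell (14 over the list alone), with a median of -2.19 (camera adjusted p = 3.81e-16, and adjusted p = 0.078 with an estimated correlation), and Myl1 changed by -3.68 ± 0.48. Untreated library 1 had 0 Xist reads, whereas every other library had Xist reads, so a difference in sex-linked transcripts is part of every comparison with untreated skin. Without untreated library 1 the comparison gave 225 higher and 208 lower genes, and limma on the deposited log2 values gave 2369 higher and 541 lower.

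**Figure D2:**
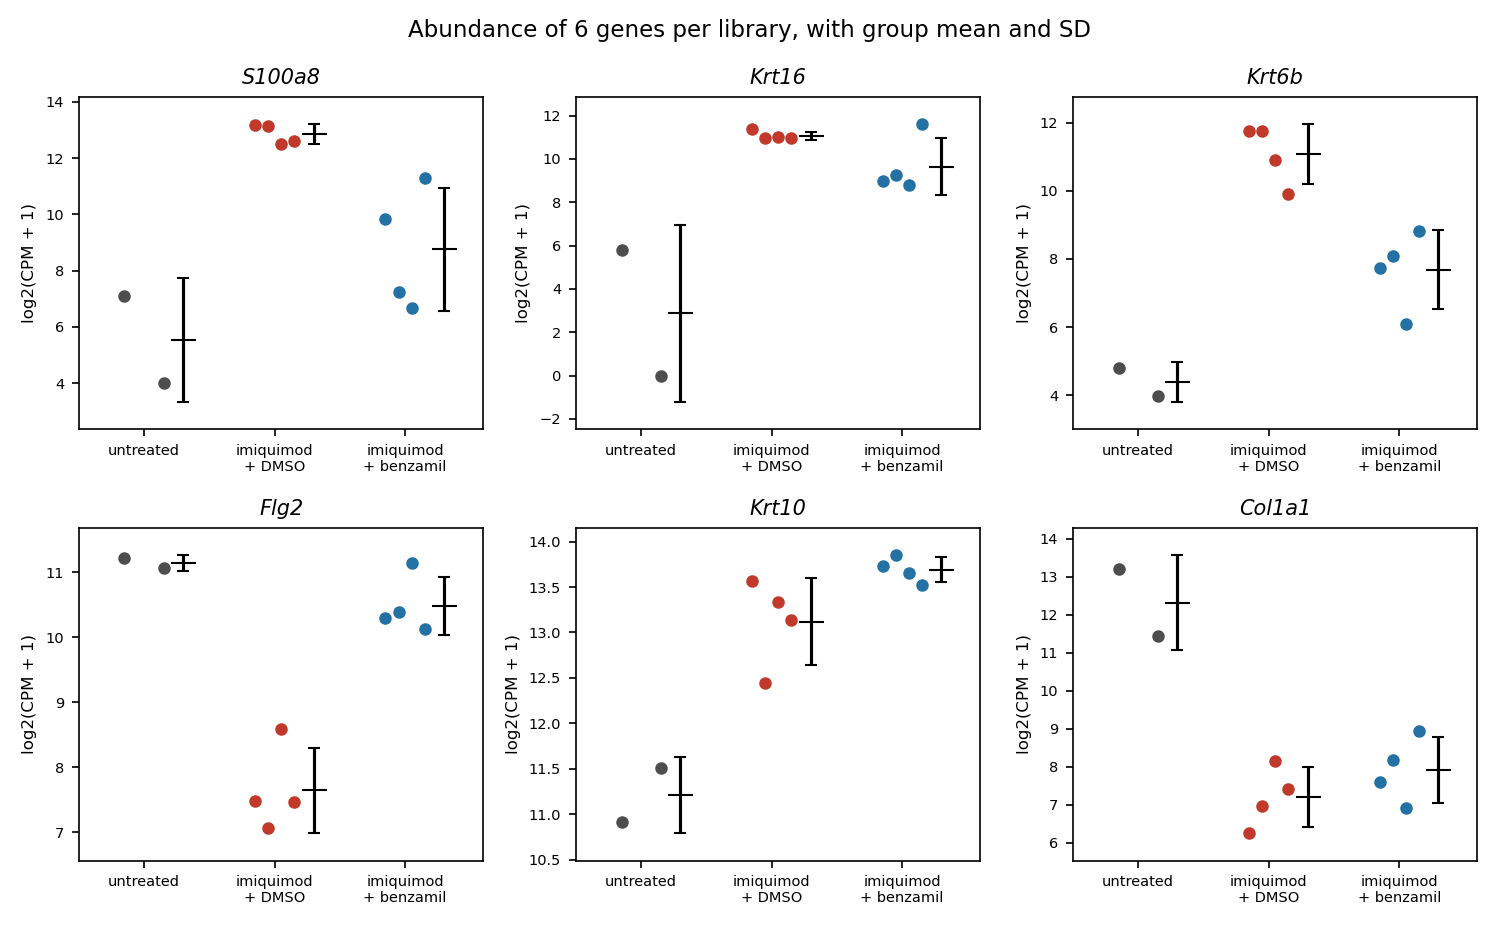
log2(CPM + 1) of 6 genes in each library, with 1 point per library and a bar for the mean ± SD of these log values, which can pass below 0 (untreated n = 2, imiquimod with DMSO n = 4, imiquimod with benzamil n = 4). Flg2 was 217 CPM on average with DMSO against 1493 with benzamil and 2266 in untreated skin, and Col1a1 was 163, 274 and 6098 CPM in the same order.

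The comparison of the benzamil group with untreated skin asked what remained different when imiquimod was given with the blocker. Krt1, a keratin of differentiating epidermis, changed by 3.70 ± 0.40 (edgeR adjusted p = 1.34e-06) and Krt10, its partner in the spinous layer, rose from 2430 ± 696 to 13250 ± 1253 CPM (2.45 ± 0.34, edgeR adjusted p = 6.32e-05, n = 2 and 4). Stfa3 was also higher (5.25 ± 0.55, edgeR adjusted p = 8.02e-07), and Col1a1 was lower (-4.51 ± 0.43, edgeR adjusted p = 2.35e-07). In all, 128 genes were higher and 82 lower.

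Differentiation genes rose in 13 of 35 (26 over the list alone), with a median of 1.65 (camera adjusted p = 6.07e-23, and adjusted p = 0.101 with an estimated correlation). Stress keratin and cornified-envelope genes rose in 12 of 25 (16 over the list alone), with a median of 5.25, or 1.89 with 14 members at their bound (camera adjusted p = 2.54e-14, and adjusted p = 0.129 with an estimated correlation). Krt16 changed by 5.32 ± 0.94 (edgeR adjusted p = 0.00119, 0.13 with limma-voom, and a log2 fold change of 4.19 without benzamil library 4), and Krt6a by 3.09 ± 0.59 (edgeR adjusted p = 0.00279, 0.074 with limma-voom and 0.05 without untreated library 1). Antimicrobial genes rose in 4 of 13 (4 over the list alone; camera adjusted p = 0.00316, and adjusted p = 0.272 with an estimated correlation). S100a9 changed by 3.84 ± 0.94 (edgeR adjusted p = 0.0194), which became 0.0789 without untreated library 1 and 0.128 without untreated library 2.

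Matrix genes fell in 9 of 14 (10 over the list alone), with a median of -2.59 (camera adjusted p = 9.95e-27, and adjusted p = 0.0805 with an estimated correlation), among them Col1a2 by -3.44 ± 0.31, Sparc by -2.78 ± 0.33 and Col6a3 by -3.42 ± 0.55. Muscle genes fell in 3 of 16 (8 over the list alone; camera adjusted p = 1.98e-09, and adjusted p = 0.188 with an estimated correlation). Barrier lipid genes rose in 2 of 19 (6 over the list alone; camera adjusted p = 8.55e-05, and adjusted p = 0.101 with an estimated correlation), and 1 of 18 cholesterol genes rose (3 over the list alone; camera adjusted p = 0.00143, and adjusted p = 0.101 with an estimated correlation). The cytokine (1 of 6 higher, 3 over the list alone, estimated-correlation adjusted p = 0.161), cell cycle (1 of 28, 3 over the list alone, 0.443) and sebaceous lists (4 of 13, 5 over the list alone, 0.443) each had a camera adjusted p of 0.023. These 3 lists lost their call without 1 library: the cytokines at 0.584 without untreated library 1, the cell cycle at 0.138 without untreated library 1 and the sebaceous list at 0.485 without untreated library 2. The 8 other testable lists did not pass, with camera adjusted p from 0.133 for basal keratinocytes to 0.928 for immediate early genes.

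Without untreated library 1 this comparison gave 63 higher and 36 lower genes, and without untreated library 2 70 and 44. Scaling by total counts alone gave 63 higher and 105 lower, 37.5% higher against 61.0%.

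Whether benzamil moved the genes that differed between the DMSO group and untreated skin was read from the overlap of these comparisons. The comparison with untreated skin mixes imiquimod with DMSO and holds a difference in sex-linked transcripts, and body site may enter it. Of the 521 genes higher in the DMSO group than in untreated skin, 269 were lower with benzamil, where independent lists would share 63.1, and 8 were higher with benzamil. Of the 443 lower genes 181 were higher with benzamil, where independent lists would share 43.9, and 1 was lower. Without untreated library 1 these opposite sets held 124 and 82 genes. S100a8, S100a9 and Krt6a were in the former set, and Flg2, Sparc, Dst, Krt15 and Myl1 in the latter.

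Across genes, which are not independent replicates, the correlation of the fold changes was -0.651 and the covariance -0.564. Both comparisons use the DMSO libraries with opposite sign, and in 20 simulations of unchanged groups the correlation averaged -0.208 and the covariance -0.0344. Their 0 opposite calls are no yardstick for the overlap, since almost no gene was called in them. Groups changed by imiquimod but not by benzamil were not simulated. The difference of the covariances was -0.530. With the DMSO libraries split 2 and 2 so that no library was shared, the 6 splits gave 121 to 168 genes higher then lower (17.6 to 38.5 for independent lists), 46 to 113 lower then higher (9.25 to 25.1), and correlations from -0.610 to -0.567. Of the genes higher in the DMSO group than in untreated skin, 99 were also higher in the benzamil group than in untreated skin. Of the genes lower in the DMSO group, 80 were also lower in the benzamil group. The DMSO and benzamil comparisons with untreated skin share the untreated libraries with the same sign, which by itself favours agreement, and no reference value for this was computed.

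**Figure D3:**
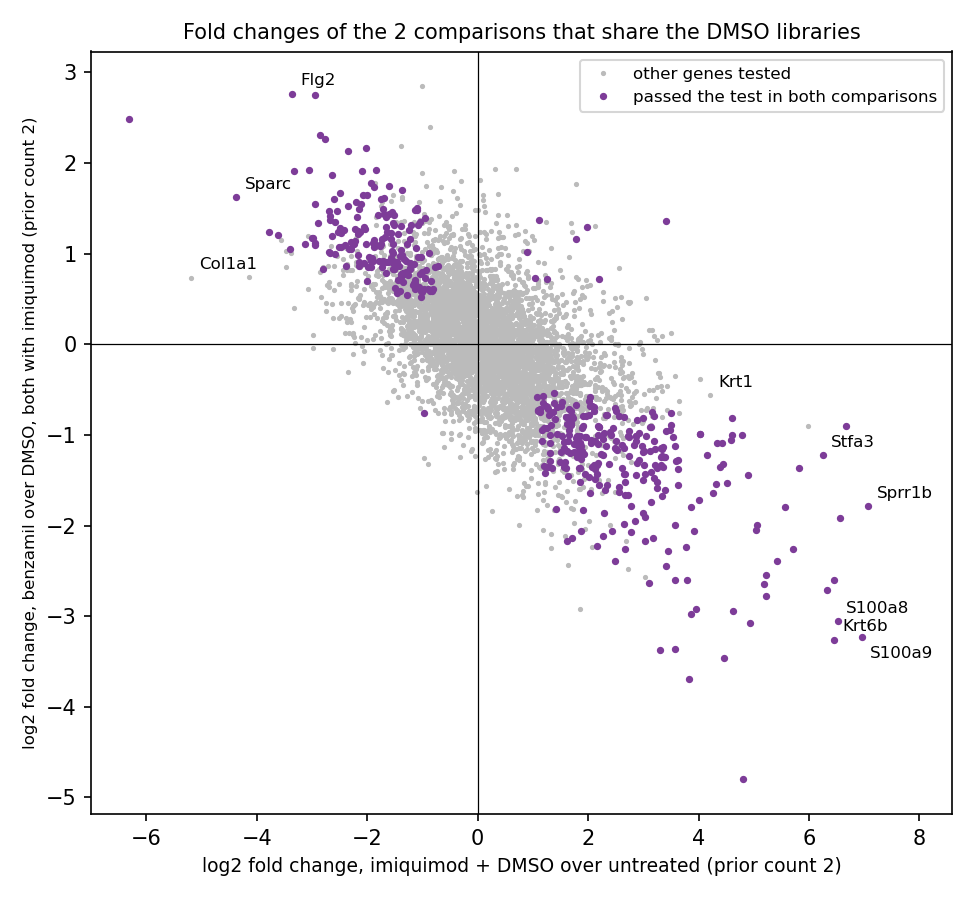
log2 fold change of imiquimod with DMSO over untreated skin (x axis) against benzamil over DMSO, both with imiquimod (y axis), for 5245 genes, each 1 point, fitted with a prior count of 2, which pulls genes with few reads toward 0. Purple points passed the test in both comparisons, and 450 of them changed in opposite directions.

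The authors' deposited table for benzamil over DMSO held 375 higher and 486 lower genes at an adjusted p under 0.05, and 808 of the 1155 genes called here were called there as well, in the same direction. The authors' deposited table for the untreated comparison, coded as untreated minus DMSO and turned here, held 324 higher and 361 lower genes, and 621 of the 964 genes called here were called there as well, in the same direction. In both, 0 genes passed in opposite directions, and Spearman's rho of the fold changes across genes was 0.996 and 0.997. Such a rank correlation does not compare sizes. For benzamil over DMSO the authors' log2 fold change of S100a8 was -1.23 against -3.09 here, while that of Flg2 was 2.45 against 2.81. Lcn2 and Il19, called here, did not pass in the authors' DESeq2 results (adjusted p = 0.258 and 0.0611).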

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

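The test of human RNA was written before its result was seen, and no test in this part was chosen afterwards.

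A library was marked where its gap to the nearest other library of its group of 4 passed Dixon's limit for the share of the group's range, which chance does in about 1 in 20 groups (5%). Of 367 groups examined 29 were marked, 7.9%. In the DMSO group, total reads were marked at 0.85, since library 1 held 938322 reads against 260207 to 362021.

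DMSO library 1 also stood apart for Krt15 (0.877, lowest), Cytl1 (0.907), Hbb-bs (0.943), Krt16 (0.855), Zbtb16 (1 of the range, with all reads in that library) and Col3a1 (0.908, lowest). DMSO library 3 was highest for Btc (0.846), Kctd2 (0.835) and the muscle genes Myh4 (0.861) and Pvalb (0.874). DMSO library 4 was lowest for Ier3 (0.852) and Dgat2 (0.848) and highest for Fabp4 (0.853) and Snrnp25 (0.908).

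Benzamil library 4 was the highest of its group in 9 marked genes: Krt16 (0.939), Lcn2 (0.885), Sprr2e (0.884), Sprr2g (0.916), Sprr2i (0.928), Il19 (0.847), Gpnmb (0.858), and Prss22 and Defb4 (1 of the range each, from 1 and 2 reads). The ratio is 1 wherever a single library holds all the reads of its group, however few. Its Krt16 level was 3113 CPM against 440 to 604 CPM in the other 3, and its Lcn2 level 79.4 CPM against 0 to 9.1 CPM. Among the other benzamil libraries, Mt4 was lowest in library 3 (0.848), Ccl20 was seen in library 3 alone and Csta3 in library 2 alone (1 of the range each, from 1 read), and library 1 was highest for Sgk1 (0.873) and Tpm2 (0.908).

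A further deposited table counts reads of these mouse libraries on human gene models. It holds 409234 reads in all, 8752 to 136930 per library, or 9.82% to 14.6% of the mouse reads, with KRT10 the gene with the most reads (7053). Human RNA in the libraries would not be bound to follow the mouse fold changes, yet across 2540 genes of the same name, which are not independent replicates, Spearman's rho of the benzamil over DMSO fold changes was 0.669 (0.607 and 0.518 for the other comparisons). This argues against human RNA as the main source, and mouse reads counted on human models may be what the table holds. No biological explanation was tested.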

How the results depend on the processing

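The filter at 100 CPM, limma on the deposited log2 values, removal of ribosomal RNA genes and leaving out benzamil libraries 3 and 4 were chosen after the data were seen, and the other settings before. Of 237 counts recomputed, 185 stayed within 1.5 times the reported one and 52 moved further. No gene called in the reported fit was called in the opposite direction under any setting. With 1 library left out, 67 of the 81 named calls of benzamil over DMSO held in every case, 51 of 86 of DMSO over untreated and 13 of 51 of benzamil over untreated, and the fits without an untreated library lost the most named calls in those comparisons (28 and 19 in DMSO over untreated, 30 and 31 in benzamil over untreated). Over these left-out fits the lists kept direction and call in 492 cases, lost the call in 16, gained it in 4 and changed sign in 13. With other settings they kept both in 227, lost the call in 36, gained it in 2 and changed sign in 5. With an estimated correlation every called list lost its call, leaving 0 in each comparison. Named genes kept both in 2376 left-out fits and 3093 others, lost the call in 240 and 203, gained it in 7 and 24 and changed sign in 25 and 19. Where only 1 untreated library remained it was assumed to vary like the other groups. Depth limits the untreated comparisons, since 3 reads equal 40.2 and 42.2 CPM there. The simulated fit of DMSO over untreated, with that depth and 2 untreated libraries together, recovered 5.43% of 2-fold changes, and the simulation does not separate depth from the number of libraries. Unless the setting removes genes, reads or libraries, the cause of a move was not tested.

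For benzamil over DMSO, the genes called higher ranged from 291 to 632 and lower from 356 to 799 with 1 library left out, for DMSO over untreated from 225 to 532 and from 208 to 448, and for benzamil over untreated from 63 to 141 and from 36 to 92. The overlap of higher then lower genes ranged from 124 to 283 and of lower then higher from 82 to 172. Without composition scaling benzamil over DMSO gave 248 higher and 1009 lower, benzamil over untreated 63 higher, and the lower then higher overlap 94. That setting shifted the median of all genes by -0.26 in benzamil over DMSO, 0.09 in DMSO over untreated and -0.16 in benzamil over untreated. Without a filter benzamil over untreated gave 200 higher. DESeq2 gave 327 higher in benzamil over DMSO, 305 higher in DMSO over untreated, and overlaps of 174 and 112. limma-voom gave 329 higher in DMSO over untreated and 51 higher in benzamil over untreated, and fits of 2 groups 77 higher in the latter. Thinning to the smallest library, with 1555 genes tested, gave 138 higher and 136 lower, 210 and 215, and 83 higher in the 3 comparisons, with overlaps of 88 and 54. The filter at 100 CPM gave 262 higher and 278 lower in benzamil over DMSO, 300 higher in DMSO over untreated, and overlaps of 145 and 113. limma on the deposited log2 values gave 2369 higher in DMSO over untreated and 485 genes higher then lower. Without benzamil libraries 3 and 4 there were 284 higher and 300 lower in benzamil over DMSO, 43 lower in benzamil over untreated, and overlaps of 177 and 120. With the DMSO libraries split, the median overlaps were 157 and 82.

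The deviations of same-numbered libraries had correlations of 0.0686, 0.000688, 0.0406 and 0.0676 for DMSO and benzamil, -0.118 and -0.0135 for DMSO and untreated, and -0.11 and 0.116 for benzamil and untreated. For DMSO and benzamil they lay among those of differently numbered libraries (-0.129 to 0.17), so no pairing was seen, but weak correlations cannot exclude one. With 2 untreated libraries the deviations are mirror images, so the other values cannot show or refute a pairing. With the number as a block the calls were 465 higher and 594 lower, 545 and 418, and 84 and 63. The block turned mt-Nd4 to 0.24 and 0.011 in DMSO and benzamil over untreated, and the mitochondrially encoded list in benzamil over untreated changed sign (camera adjusted p = 0.878).

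None of the named genes and lists that changed sign had passed the test. Among all called genes of DMSO over untreated, 7 changed sign without untreated library 1 and 3 without untreated library 2, and 0 in any other setting or comparison. In benzamil over DMSO, without composition scaling Thy1 was -0.11 and Sox9 -0.13, and Sox9 was -0.022 with limma on log2 values. Epcam was 0.0035 with a filter at 10 CPM, 0.021 with 2 groups, 0.00083 at 100 CPM, 0.052 without benzamil libraries 3 and 4, and -0.19 to 0.16 with 1 library left out (0.031, 0.044 and 0.023 without DMSO 1, DMSO 4 and benzamil 2). Scnn1a was 0.0059 with limma-voom and -0.27 to 0.094 with 1 left out (0.06 and 0.014 without benzamil 2 and 3). Sgk1 was 0.26 without benzamil 3 and 4 and -0.67 to 0.084 with 1 left out (0.016 and 0.053 without benzamil 3 and 4 singly). Hbb-bs was 0.21 without benzamil 3 and 4 and -0.91 to 1.10 with 1 left out (0.088 without benzamil 3), and Il7r -0.036 to 0.93. The barrier lipid list had an adjusted p of 0.591 to 0.976 with 1 left out and 0.99 without benzamil 3 and 4, where the cholesterol list had 0.978. In DMSO over untreated, mt-Nd4 was 0.0029 without a filter, 0.035 with limma on log2 values and -0.70 to 0.82 with 1 left out, Hbb-bs -0.46 to 1.83, the sodium transport list 0.529 to 0.991 and the sebaceous list 0.135 to 0.991.

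In benzamil over untreated, Gata3 was 0.064 without a filter, 0.0204 with a filter at 10 CPM and -0.14 to 0.022 with 1 left out. Lcn2 was -0.13 with limma-voom and -0.14 to 5.52 with 1 left out. Jund was -0.28 after thinning. mt-Nd4 was 0.068 without benzamil 3 and 4 and -0.83 to 0.67 with 1 left out. The ranges with 1 left out were -0.39 to 2.03 for Ccl6 (-0.10 without benzamil 4), -0.79 to 0.17 for Cd74, -0.096 to 1.60 for Hbb-bs, -1.12 to 0.014 for Il33, -0.47 to 0.0101 for mt-Nd1 and -0.82 to 0.23 for Nfkbia. The adjusted p of the lists ranged from 0.712 to 0.972 for sodium transport (0.964 and 0.752 without benzamil 2 and untreated 1), 0.133 to 0.85 for mitochondrially encoded genes (0.728 without untreated 2, 0.742 without benzamil 3 and 4) and 0.756 to 0.983 for immediate early genes (0.842 without benzamil 3 and 4).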

Other observations

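The tests of depth on all members of a pattern, of transcript length and GC content, of the share of non-epidermal tissue and of body site, and the 9 gene lists of the following paragraphs with their matched random lists, were chosen after results had been seen.

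With benzamil over DMSO, of 72 tested cytosolic ribosomal protein genes 29 fell and 4 rose, with a median log2 fold change of -0.55 (camera adjusted p = 1.45e-05, and adjusted p = 0.317 with an estimated correlation), and Rps2 changed by -2.39 ± 0.41. Of 71 nuclear-encoded respiratory chain genes 22 fell and 1 rose, with a median of -0.50 (camera adjusted p = 1.46e-05, and adjusted p = 0.303 with an estimated correlation), and Ndufa4 changed by -2.88 ± 0.37 and Atp5g3 by -1.87 ± 0.27. In DMSO over untreated 15 of the 71 rose and 0 fell (camera adjusted p = 0.000231, and adjusted p = 0.233 with an estimated correlation). Chaperonin and heat-shock genes fell in 10 of 22 (camera adjusted p = 0.000236, and adjusted p = 0.208 with an estimated correlation), and the endoplasmic reticulum chaperone Hspa5 changed by -0.95 ± 0.20. Glutathione and thioredoxin genes fell in 4 of 13 and rose in 1, and unfolded protein response genes fell in 3 of 7 (camera adjusted p = 0.00856 each, and adjusted p = 0.182 and 0.208 with an estimated correlation). Proteasome genes fell in 7 of 32 (camera adjusted p = 0.0564), aminoacyl-tRNA synthetases in 2 of 13 (0.244), and eicosanoid enzymes in 2 of 7 with 1 higher (0.12).

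These falls came with differences that RNA quality could bring, though it was not measured. Fold changes followed transcript length (Spearman's rho 0.171 for benzamil over DMSO and -0.245 for DMSO over untreated, over 5219 genes), and ribosomal RNA genes took 31.0% to 45.7% of reads with benzamil against 22.1% to 28.8% with DMSO. Mitochondrial mt-Rnr2 alone took 24.0% to 39.6% with benzamil against 13.5% to 19.3% with DMSO, so that gap lay mainly in a single mitochondrial transcript. Of 1000 random lists matched on transcript length, GC content and level, those with a median as low in benzamil over DMSO numbered 0 for ribosomal proteins, 3 for the respiratory chain, 6 for chaperonin and heat-shock genes, 8 for the unfolded protein response, 271 for glutathione and thioredoxin genes, 298 for the proteasome, 99 for aminoacyl-tRNA synthetases and 105 for eicosanoid enzymes. In DMSO over untreated, those as high numbered 489 for ribosomal proteins and 239 for the proteasome, which had both passed camera (adjusted p = 0.0267, and 0.564 and 0.233 with an estimated correlation). They numbered 2 for the respiratory chain, 10 for chaperonin and heat-shock genes, 69 for aminoacyl-tRNA synthetases, 144 for glutathione and thioredoxin genes, 197 for the unfolded protein response and 21 for eicosanoid enzymes. The chaperonin, aminoacyl-tRNA and glutathione lists had passed camera there as well (adjusted p = 0.0124, 0.0316 and 0.0267, and 0.233 each with an estimated correlation). Random lists draw genes singly, whereas members of a list vary together between libraries. These counts therefore measure the spread between genes and not between samples, and they are no test of the groups. A difference in RNA quality that does not follow length, GC content or level was not tested.

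The 5 tested ligands of the epidermal growth factor receptor did not pass as a list (camera adjusted p = 0.0595). Their median of -1.73 was matched by 0 of 1000 such random lists, and 6 were as high as their median in DMSO over untreated. The list was chosen after values such as those of Epgn and Btc had been seen, so these counts give it no independent support. Epgn (-4.00 ± 0.60), Tgfa (-2.46 ± 0.41) and Hbegf (-1.73 ± 0.36) fell with benzamil while Btc rose (2.88 ± 0.46), and Ereg gave -0.38 ± 0.27.

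Genes higher in the DMSO group than in untreated skin tended to be lower with benzamil. Of the 35 splits of the 8 treated libraries into 4 and 4, only 1, the real one, called as many genes (1155, against at most 2 in another split). This is the smallest share that 35 splits can give, so chance in the assignment of these libraries is unlikely but not excluded. Every other split mixes the groups and widens the spread within them, so any difference between the groups, whatever its cause, would favour the real split. Chance differences between animals stay open, should the libraries not be separate animals. Shared DMSO libraries would bring the median benzamil fold change of these genes to about 0 once no library is shared, and it stayed at -0.71 or below in each of the 6 splits. Lower depth with benzamil would remove it after thinning, where it was -0.843 over all 521 genes (-0.82 unthinned, 88.1% negative). A bias of length, GC content and level would give matched lists a median like the -0.82 of all 521 genes (520 with a known length and GC content), which 0 of 1000 did (lowest -0.06). Both tests reuse the DMSO libraries in which the 521 genes were selected as high, and the matched lists were not so selected. Neither test alone can therefore set its explanation aside. A treatment effect on the response to imiquimod with DMSO is a hypothesis that stays open, and it may include a difference in RNA quality between the groups, which was not measured. Whether the treated groups shared the same vehicle was not examined. Ribosomal RNA genes took up to 45.7% of reads with benzamil, but mitochondrial mt-Rnr2 made up 39.6% of reads in that library.

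Matrix and muscle genes were lower in the DMSO group than in untreated skin. Lower depth of the untreated libraries would remove this after thinning, and the medians of all 14 matrix and 16 muscle genes were then -2.59 and -2.41, with every member negative. A lower share of all non-epidermal tissue in the treated samples would lower these lists alike, and by library the matrix score minus the muscle score changed by -0.265 with overlapping libraries (-0.66 to 1.15 with DMSO, 0.051 and 0.662 untreated). That share and an effect on the tissue cannot be told apart, because the libraries are few and vary more than this, and of 20 members of 9 other non-epidermal lists 7 were called lower and 2 higher. Body site and group cannot be told apart, because 0 of 19 trunk homeobox genes were in the table, at a depth where such genes might be missed. An effect of imiquimod with DMSO on dermal transcripts stays open, as a hypothesis.

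Sex-linked transcripts differed between the untreated libraries. Untreated library 1 had 0 Xist reads and 10 Ddx3y reads, and untreated library 2 had 40 Xist reads (562 CPM of the library total, without TMM scaling) and 0 Ddx3y reads. The other 8 libraries had 268 to 466 CPM of Xist on the same scale, and the DMSO libraries had 0 Ddx3y reads. This difference enters every comparison with untreated skin and was not separated from that of treatment.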
